A study of Mus musculus with 36 samples.

How the data were processed

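RNA of sorted mouse monocytes and macrophages was measured on Affymetrix Mouse Gene 1.0 ST arrays, with 36 arrays in 10 groups of 3 or 4. The deposited values are log2 expression values that the authors summarised and normalized between arrays by RMA; the version of RMA and its settings are not given. The values ran from 1.93 to 14.42, and the medians of the arrays from 5.802 to 5.988. A second deposited table holds the same 36 columns and 45 further columns of other series, which were not used. Its values for the 36 arrays differed from the first table by 0, so only one was analysed. For arrays no read depth exists, and the number of arrays limits the precision. The 3 day-3 arrays carry the replicate numbers 1, 1.1 and 1.2. The yolk sac group was taken from the sample titles, since another label of these samples names the liver.

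The tables hold 35556 probe sets. Of these, 21789 had 1 gene symbol, 1621 had several and 12146 were not in the annotation. For each gene the probe set with the highest mean was used, giving 19938 genes. A gene was tested where its highest group mean reached the median of all values of such probe sets, 6.22, which left 11360 genes. Means per group were fitted to all 36 arrays in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, 26 residual and 4.86 prior degrees of freedom). P-values were two-sided and adjusted by Benjamini-Hochberg over all genes of a comparison, and a gene was called at an adjusted p under 0.05 and a log2 change of at least 1. Tables and plots were made with the data.table package (1.17.8), Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. The groups, the comparisons, the tests, the gene lists, the rule for named genes and the alternatives not described as added were chosen before the data were examined.

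Comparisons were made between neighbouring stages or sorted fractions, between the end points of both courses, and from start to end of each course. The difference of the start-to-end changes was tested as an interaction. The genes named are the course genes (Clec4f, Adgre1, Timd4, Vsig4, Nr1h3, Id3, Spic, Cd5l and Ccr2), the 6 largest rises and 6 largest falls among called genes with non-overlapping arrays and a proper name, and up to 2 called members per direction of each list. Ly6c2, also planned, had no probe set of its own. Mki67 outside its list's named members, and group means of genes of the rule in other groups, were added after their values were seen.

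The 30 gene lists were tested with camera in limma, with the inter-gene correlation preset at 0.01 and, beside it, estimated from the residuals. P-values were adjusted over 360 tests of lists and comparisons. They cover Kupffer cell identity, pan-macrophage and monocyte genes, cell cycle, LXR targets, cholesterol biosynthesis, Notch, BMP and TGF-beta signalling, iron and heme handling, MHC class II, inflammatory cytokines, interferon-stimulated genes, immediate early and stress genes, complement, scavenger receptors, ribosome, oxidative phosphorylation, glycolysis and hypoxia, fatty acid handling, lysosome and adhesion. Markers of hepatocytes, erythroid, endothelial and stellate cells, neutrophils and their precursors, B, T and NK cells, dendritic cells, and megakaryocytes and mast cells were included, as was a list of yolk sac and embryonic macrophage genes. Some lists share members: of the 31 measured Kupffer cell genes 16 are also in another list, none of them in the hepatocyte or endothelial lists. Random relabelling of all arrays, 100 times, gave a median of 110 and at most 149 called lists with the preset correlation but at most 0 with an estimated one, so the estimated p is given with each list.

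The test was checked on simulated data with the array numbers of 3 comparisons and 200 changed genes among 11360. Each gene was drawn independently, with its SD pooled over all groups. Changes of 1.5, 2 and 3 on the log2 scale were recovered in 98.5% to 100% of cases with 0 or 1 false calls per comparison. A changed list was called each time, and 0 of 10 unchanged lists were. Since the genes were drawn independently, this does not show how correlated genes affect the list test.

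Replicate numbers were checked as pairs by correlating residuals of arrays with the same number. Only the Clec4f+ and Clec4f- fractions of E17 paired, with correlations of 0.196 to 0.24 in each of the 4 pairs, and for these a block was fitted beside the main model.

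Alternatives were quantile normalization, centring of arrays, no filter or a stricter filter on dim probes, the mean over probe sets, a prior with trend and robust settings, array weights, no minimum change, a fit of the compared groups only, the replicate number as a block, leaving out each replicate in turn, an estimated correlation and the rotation test fry. Added after seeing the data were the endothelial and hepatocyte scores as covariates and a fit without E18 replicate 2 and birth replicate 3. Also added were a fit without the yolk sac arrays, both scalings for the gene lists, and list tests in fits of only the E17 fractions. Those list tests were made with and without the block and adjusted over 30 lists. The scores are means over a list of gene values centred over the arrays. As covariates they act through variation within groups, so the fit extrapolates where the scores of the compared groups do not overlap. The exchangeability of arrays was tested by refitting all splits, or 100 with the real one counted among them.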

Results

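Gene expression was measured on arrays in 36 samples of sorted C57BL/6 mouse monocytes and macrophages, most from the liver. Kupffer cells are the resident macrophages of the liver, and Clec4f is a lectin that marks them. The samples form a repopulation course, in which cells refill the liver after Kupffer cells have been depleted, and a fetal course. The repopulation course held day-1 liver monocytes (n = 3), day-3 F4/80+ macrophages (n = 3) and day-7 Clec4f+ macrophages (n = 3). The fetal course held E11 yolk sac macrophages (n = 3), Clec4f- macrophages of E12, E15 and E17 (n = 4 each), Clec4f+ macrophages of E17 and E18 (n = 4 each) and Kupffer cells at birth (n = 4). The sort marker therefore changes with the stage in both courses. Each value is a log2 expression value with the SD of the arrays of its group, and each change is a difference of group means on the log2 scale with its standard error from limma. The number of arrays limits the precision. The labels do not say whether replicates came from separate animals, so p-values measure only the spread between these samples. The day-3 arrays are numbered 1, 1.1 and 1.2, and whether they are repeats of 1 sample is not known; if they are, the n, SDs, standard errors and p-values of both day-3 comparisons do not hold. A gene was called when its adjusted p was under 0.05 and its change at least 1, and "rose" and "fell" are used of called genes and lists. In the called genes named here for a comparison of 2 groups, all arrays of one group lay above all arrays of the other, except Mcpt8 at E17, Gzma from E17 to E18 and Clec4f between the end points. A gene list is described by how many of its measured members rose or fell over all 11360 genes tested, and its test compares the list with all other genes. Counts adjusted over the list alone were equal to these unless stated. No called list had a median or mean change of opposite sign to its test. A level under 6.22, the limit used for dim probes, is not separated from background, and the size of a change from or to such a level is limited by it. This holds for 176 of the 497 changes of named and called genes between 2 groups. Genomic positions were not part of the files.

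**Figure D1:**
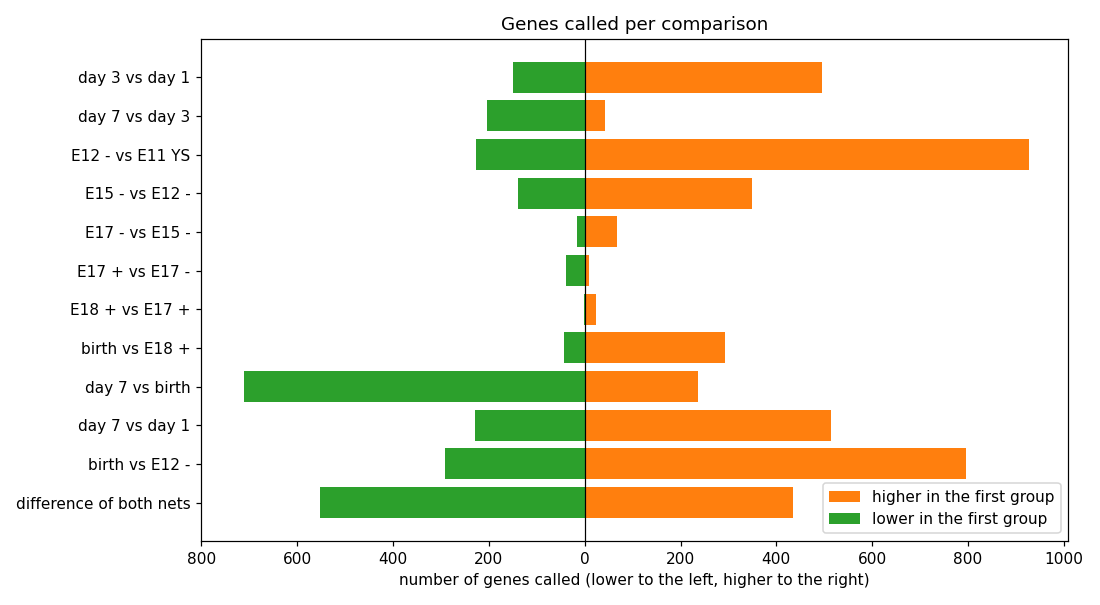
Number of genes called higher (to the right) and lower (to the left) in each comparison, counted in genes. The 1153 genes of the step from yolk sac to E12 and the 24 of the step from E17 to E18 are the ends of the range among the steps between neighbouring stages.

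The first step of repopulation, from day-1 monocytes to day-3 F4/80+ macrophages, asks what a monocyte gains on becoming a liver macrophage. Kupffer cell genes rose early and steeply. Cd5l, a secreted protein of liver macrophages, went from 7.41 ± 0.54 to 12.33 ± 0.12 (SD, n = 3 each), 30.4-fold. Clec1b rose by 4.79 ± 0.13 (SE), Vsig4, a complement receptor of Kupffer cells, by 4.43 ± 0.24, and Cd207 by 4.24 ± 0.19. Of 31 measured members of the Kupffer cell list 17 rose and none fell (adjusted p = 5.77e-05 with an estimated correlation). Proliferation genes moved as a block: 30 of 34 cell cycle members rose, Bub1 by 3.51 ± 0.25 and Ccnb2 by 3.22 ± 0.22 (adjusted p = 0.00196 with an estimated correlation). Monocyte genes fell, 9 of 17, led by Chil3, a chitinase-like protein, with -5.10 ± 0.37 and S100a4 with -3.06 ± 0.32 (adjusted p = 0.00118 with an estimated correlation). The neutrophil and granulocyte precursor list fell with 8 of 17 members, among them S100a8 (-4.62 ± 0.62) and S100a9 (-4.24 ± 0.63), at an adjusted p = 0.0365 with an estimated correlation. In the immediate early and stress list, 3 of 20 fell, among them Nr4a1 (-2.01 ± 0.19) and Klf4 (-1.08 ± 0.17), at an adjusted p = 0.0108 with an estimated correlation. The integrin subunit genes Itgax (-2.34 ± 0.21) and Itgam (-2.18 ± 0.22) fell, whereas the cytokine gene Il1a rose by 3.09 ± 0.15 and the mannose receptor gene Mrc1 by 1.95 ± 0.11. Ccr2, the receptor that guides monocytes out of the blood, was lower by less than the minimum change (-0.83 ± 0.21), as was Spic (-0.44 ± 0.14), a transcription factor of iron-recycling macrophages that was already at 11.17 ± 0.22 on day 1. Markers of endothelial cells moved with the Kupffer cell list: 18 of 19 rose, Bmp2 by 3.09 ± 0.30 and Clec4g, a lectin of liver sinusoidal endothelium, by 2.81 ± 0.28. The call of that list was lost with an estimated correlation (adjusted p = 0.0519). In total 645 genes were called, 495 higher and 150 lower.

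From day 3 to day 7 the course asks how repopulating cells become Clec4f+ cells. Proliferation genes fell back: 31 of 34 cell cycle members fell, Ccna2 by 2.71 ± 0.19 and Bub1 by 2.70 ± 0.25 (adjusted p = 0.000919 with an estimated correlation). Mki67, a proliferation marker, stood at 6.79 ± 0.41, 8.77 ± 0.18 and 6.93 ± 0.27 on days 1, 3 and 7. A further group of Kupffer cell genes rose, 8 of 31, with Vsig4 up 3.02 ± 0.24 and the complement gene C6 up 2.27 ± 0.16 (adjusted p = 0.000299 with an estimated correlation). Clec4f, the sort marker of the day-7 cells, rose by 2.55 ± 0.32, and Chp2, Ephx1 and Pcolce2 rose by 2.52 ± 0.17, 2.10 ± 0.29 and 2.09 ± 0.23. Cd5l, at 12.62 ± 0.03 on day 7, differed little from day 3 (0.29 ± 0.24, adjusted p = 0.452). The complement list rose with 2 of 16 members, Vsig4 and C6, which the Kupffer cell list also holds (adjusted p = 0.00268 with an estimated correlation). The pan-macrophage list moved up by a median of 0.35 with 1 member called, Trem2, which fell 2.15-fold (adjusted p = 0.0187 with an estimated correlation). The scavenger and efferocytosis list moved up by a median of 0.24 with no member called (adjusted p = 0.0187 with an estimated correlation). Timd4, a phosphatidylserine receptor of embryo-derived Kupffer cells, reached only 6.84 ± 0.08, and Ccr2 stayed at 10.39 ± 0.10. In total 246 genes were called, 43 higher and 203 lower.

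Macrophages of the E11 yolk sac and of the E12 liver were compared because the yolk sac is an early source of tissue macrophages. Genes of granulocyte and granulocyte-precursor granules were far higher at E12. Prg2, a granule protein of eosinophils, rose by 5.77 ± 0.44 from a dim 5.51 ± 0.30, S100a9 by 5.08 ± 0.59, Ngp by 4.58 ± 0.18 and Mpo by 4.41 ± 0.22, and 11 of 17 members of the neutrophil and precursor list rose. Its adjusted p was 0.132 with an estimated correlation. Interferon-stimulated genes were lower at E12 in 17 of 18 members, Rsad2 by a change of -3.44 ± 0.27 and Ifit2 by -3.24 ± 0.27 (adjusted p = 0.0519 with an estimated correlation). Of the Kupffer cell list 14 of 31 rose and 3 fell (adjusted p = 0.134 with an estimated correlation). Id3, a transcriptional regulator needed for Kupffer cells, went from a dim 6.14 ± 1.25 (n = 3) to 9.32 ± 0.11 (n = 4), a rise of 3.18 ± 0.28. Its yolk sac arrays were spread widely, at 4.987, 5.954 and 7.468. Id1 rose by 2.61 ± 0.14, Spic by 2.31 ± 0.13 and Nr1h3, the nuclear receptor LXR alpha, by 1.34 ± 0.12, while Cd163 (-1.58 ± 0.20) and the folate receptor gene Folr2 (-1.38 ± 0.13) fell. In the cell cycle list 19 of 34 rose, Cenpe by 2.78 ± 0.17 (adjusted p = 0.138 with an estimated correlation). The adhesion and integrin list rose with 9 of 23 members, Cdh5 by 3.77 ± 0.14 and Itgal by 3.14 ± 0.09 (adjusted p = 0.0297 with an estimated correlation), and the complement list fell with 5 of 16 members against 2 that rose, C2 by -2.53 ± 0.19 and Cfb by -1.69 ± 0.19 (adjusted p = 0.0316 with an estimated correlation). Markers of hepatocytes, including genes that yolk sac endoderm also expresses, moved with the tissue: 8 of 16 fell at E12, Afp by 3.23 ± 0.32 and Ttr by 3.03 ± 0.27 (adjusted p = 0.161 with an estimated correlation). Of the endothelial markers 8 of 19 rose (adjusted p = 0.624 with an estimated correlation). In total 1153 genes were called, 927 higher and 226 lower. The median of all genes differed by 0.15 between the groups, and quantile normalization of the arrays moved it to -0.02 with 882 genes called, 63.9% of them higher in place of 80.4%. Tissue, stage and preparation differ together in this comparison.

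From E12 to E15, within Clec4f- macrophages of the fetal liver, the Kupffer cell programme came up. Of the Kupffer cell list 21 of 31 members rose and 1 fell (adjusted p = 8.69e-07 with an estimated correlation): Clec1b rose by 3.18 ± 0.11, Cd5l by 3.07 ± 0.21, Vsig4 by 2.99 ± 0.21 and Spic by 2.12 ± 0.12, and Ednrb fell by 1.59 ± 0.19. The LXR target and lipid efflux list rose with 3 of 17 members, Scd1 by 2.86 ± 0.16 (adjusted p = 0.00248 with an estimated correlation). The iron and heme handling list rose with 3 of 19 members, among them the iron exporter gene Slc40a1 2.29-fold (adjusted p = 0.00248 with an estimated correlation). MHC class II genes rose in 4 of 12 members, with H2-Aa at 5.15 ± 0.71 on E12 and 9.13 ± 0.33 on E15 (adjusted p = 0.0154 with an estimated correlation). Genes known from microglia and embryonic macrophages went the other way: Fcrls fell by 3.11 ± 0.26, Gpr34 by 2.80 ± 0.14 and Olfml3 by 2.69 ± 0.19, although the embryonic macrophage list, with 5 of 24 lower, had an adjusted p = 0.0631 with an estimated correlation. The immediate early and stress list fell with 3 of 20 members, Fosb by 1.51 ± 0.14 (adjusted p = 0.024 with an estimated correlation). Markers of other liver cells rose in the same arrays. These were 10 of 16 erythroid markers, with 1 that fell (Rhag up 2.78 ± 0.20, adjusted p = 0.00194 with an estimated correlation), 10 of 16 hepatocyte markers (Alb up 3.09 ± 0.30, adjusted p = 0.048 with an estimated correlation), and 4 of 12 B, T and NK cell markers (Vpreb1, of early B cells, up 3.41 ± 0.32, adjusted p = 0.024 with an estimated correlation). In the last of these lists 5 were called when adjusted over the list alone. Of the endothelial markers 14 of 19 rose, Clec4g by 2.93 ± 0.24 and Stab2 by 2.43 ± 0.24 (adjusted p = 0.079 with an estimated correlation). In total 488 genes were called, 349 higher and 139 lower. With the endothelial and hepatocyte scores as covariates, an alternative chosen after seeing the data, 385 were called, 199 higher and 186 lower.

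From E15 to E17, still among Clec4f- cells, fewer genes moved. Vsig4 rose by 2.19 ± 0.21 and Cd163 by 1.68 ± 0.18, 2 of the 4 Kupffer cell list members that rose out of 31 (adjusted p = 0.00252 with an estimated correlation). Clec4f rose by 1.63 ± 0.28, to 9.26 ± 0.25, although the gate excludes cells with its protein. MHC class II genes rose in 5 of 12 members, H2-Ab1 by 1.81 ± 0.23 and H2-Eb1 by 1.40 ± 0.19 (adjusted p = 0.000806 with an estimated correlation). The embryonic globin genes Hbb-y and Hba-x fell by 3.15 ± 0.26 and 1.57 ± 0.25, 2 of the 3 erythroid markers that fell out of 16 (adjusted p = 0.0102 with an estimated correlation). B, T and NK cell markers rose in 7 of 12, Gzma by 2.65 ± 0.39 and Vpreb3 by 2.07 ± 0.19 (adjusted p = 0.000806 with an estimated correlation). Interferon-stimulated genes were higher in 6 of 18, Oasl2 by 1.30 ± 0.24 (adjusted p = 0.0633 with an estimated correlation). The cell cycle list fell by a median of -0.44 with no member called (adjusted p = 0.048 with an estimated correlation), and the immediate early and stress list rose by a median of 0.46, again with no member called (adjusted p = 0.00247 with an estimated correlation). Neutrophil markers were higher in 5 of 17, Mmp8 by 2.07 ± 0.33 (adjusted p = 0.0838 with an estimated correlation), and the endothelial list had a median change of -0.44 (adjusted p = 0.527 with an estimated correlation). In total 83 genes were called, 68 higher and 15 lower.

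At E17 the cells were sorted by the marker itself, so that Clec4f+ and Clec4f- macrophages of the same stage could be compared. Clec4f was higher by 2.21 ± 0.28 in the Clec4f+ cells, which the gate sets. Beside it the scavenger receptor gene Cd209f rose by 1.60 ± 0.34, Pcolce2 by 1.23 ± 0.20 and Chp2 by 1.18 ± 0.15, while Vsig4 differed by just under the minimum (0.99 ± 0.21). The Kupffer cell list was higher in Clec4f+ cells by a median of 0.38 with 2 of 31 members called higher and 1 lower (adjusted p = 0.000287 with an estimated correlation). More genes were lower than higher. F13a1 was lower by a change of -2.46 ± 0.26, the chemokine receptor genes Ccr1 and Ccr2 by -2.20 ± 0.24 and -1.71 ± 0.18, and S100a4 by -2.10 ± 0.28. Monocyte genes fell in 3 of 17 (adjusted p = 0.021 with an estimated correlation). MHC class II genes were lower in 4 of 12, H2-Aa by -1.23 ± 0.26 (adjusted p = 0.0513 with an estimated correlation). Higher without any member called were the LXR target list (median 0.24, adjusted p = 0.00299 with an estimated correlation), the iron and heme list (median 0.15, adjusted p = 0.0108) and the lysosome list (median 0.20, adjusted p = 0.00687). The scavenger receptor list was higher with 1 of 22 called (adjusted p = 0.00767 with an estimated correlation), and the pan-macrophage list with none called (adjusted p = 0.0185). B, T and NK cell markers moved with the gate: 6 of 12 were lower in Clec4f+ cells, Gzma by -2.15 ± 0.39 (adjusted p = 0.00151 with an estimated correlation). Megakaryocyte and mast cell markers were lower in 3 of 12, Mcpt8 by -1.74 ± 0.39 (adjusted p = 0.0512 with an estimated correlation). In total 47 genes were called, 9 higher and 38 lower. With the replicate numbers as a block, 48 genes were called and 47 were shared. With the preset correlation, and in a fit of only these 2 groups without the block, chosen after seeing the data, the complement list (adjusted p = 0.022, then 0.0508) lost its call, as did the endothelial list, lower in Clec4f+ cells by a median of -0.22 (0.0407, then 0.081, and 2.51e-05 with the block). The hepatocyte (0.109, then 0.0134), fatty acid (0.0504, then 0.0191) and dendritic cell lists (0.056, then 0.0456) gained one. None of these 5 lists was called with an estimated correlation in the fit of all groups (0.16, 0.65, 0.624, 0.335 and 0.234). In the fit of only these 2 groups with an estimated correlation limma called 7 of 30 lists without the block and 0 with it (8 at an unadjusted p under 0.05), where the Kupffer cell list had an adjusted p = 0.127. The cell cycle score was 0.00 ± 0.06 in Clec4f+ and 0.34 ± 0.09 in Clec4f- cells (SD). In the fit of all groups camera called this list lower with the preset correlation (adjusted p = 2.56e-13) but not with an estimated one. In the fit of only these 2 groups its adjusted p with an estimated correlation was 0.0355 without and 0.0748 with the block.

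Between Clec4f+ cells of E17 and E18 little moved. Serpina1c, an antiprotease of hepatocytes, rose by 1.65 ± 0.31, Adh1 by 1.45 ± 0.22 and the fibrinogen genes Fgg and Fgb by 1.40 ± 0.30 and 1.28 ± 0.32. Hepatocyte markers were higher in 3 of 16, or 4 when adjusted over the list alone (adjusted p = 0.0519 with an estimated correlation). Interferon-stimulated genes were higher in 4 of 18, or 5 when adjusted over the list alone, with Ifit2 up 1.29 ± 0.25 and Rsad2 up 1.19 ± 0.25 (adjusted p = 0.0519 with an estimated correlation). The B, T and NK cell list rose with 1 of 12 called, Gzma by 1.64 ± 0.39 (adjusted p = 0.0108 with an estimated correlation), the cholesterol biosynthesis list rose by a median of 0.25 with no member called (adjusted p = 0.024), and the immediate early and stress list fell by a median of -0.28 (adjusted p = 0.0496). No course gene was called, with Clec4f at 11.46 ± 0.13 and 11.54 ± 0.10. The endothelial list had a median change of 0.67 (adjusted p = 0.136 with an estimated correlation), with 1 member called when adjusted over the list alone, as was 1 of the dendritic cell list. In total 24 genes were called, 23 higher and 1 lower. The count was 10 when only these 2 groups were fitted and 11 with the replicate numbers as a block. It was 12, 11 or 43 without E18 replicate 1, 2 or 3. With the endothelial and hepatocyte scores as covariates, chosen after seeing the data, limma called 0 genes (1184 at an unadjusted p under 0.05). The endothelial scores were -0.613 to 0.128 at E17 and 0.215 to 0.635 at E18. The hepatocyte scores were -0.345 to -0.046 and 0.282 to 0.698. Since neither score overlaps, this fit extrapolates and cannot decide whether such RNA caused the changes.

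The step from E18 Clec4f+ macrophages to Kupffer cells at birth closes the fetal course. Trem1 rose by 2.83 ± 0.33, the B cell gene Ms4a1 by 2.79 ± 0.25, Hamp, the iron hormone made by hepatocytes, by 2.67 ± 0.43, and Pdk4, Igfbp1 and Fgl1 by 2.53 ± 0.27, 2.48 ± 0.24 and 2.46 ± 0.32. Erythroid markers fell in 8 of 16, Hbb-y by 2.05 ± 0.26 and Alas2, of heme synthesis, by 1.68 ± 0.16 (adjusted p = 0.00365 with an estimated correlation). The Kupffer cell list fell by a median of -0.36 although its 1 called member, Ednrb, rose by 1.59 ± 0.19 (adjusted p = 0.0178 with an estimated correlation). The LXR target list fell by a median of -0.30 (adjusted p = 0.0328 with an estimated correlation). The iron and heme list fell by -0.30 with Tfrc, the transferrin receptor gene, called at -1.28 ± 0.16 (adjusted p = 0.0154). Cd209f fell by 1.85 ± 0.34, and Cd74, of MHC class II, rose by 1.32 ± 0.16. Markers of hepatocytes and endothelium moved with birth: 13 of 16 hepatocyte markers rose, Fgb 4.01-fold and Fga by 1.81 ± 0.22 (adjusted p = 0.0512 with an estimated correlation), and 15 of 19 endothelial markers rose, Bmp2 by 2.14 ± 0.26 and Emcn by 1.81 ± 0.29 (adjusted p = 0.115 with an estimated correlation). Stellate cell and fibroblast markers were higher in 3 of 12, Dcn by 1.43 ± 0.26 (adjusted p = 0.211 with an estimated correlation). Also higher were 3 of 12 B, T and NK cell markers (adjusted p = 0.116), 2 of 13 dendritic cell markers (0.0854), 2 of 12 megakaryocyte and mast cell markers (0.155) and 5 of 17 neutrophil markers (0.327), each with an estimated correlation. In total 336 genes were called, 292 higher and 44 lower. With the endothelial and hepatocyte scores of each array as covariates, an alternative chosen after seeing the data, 109 were.

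**Figure D2:**
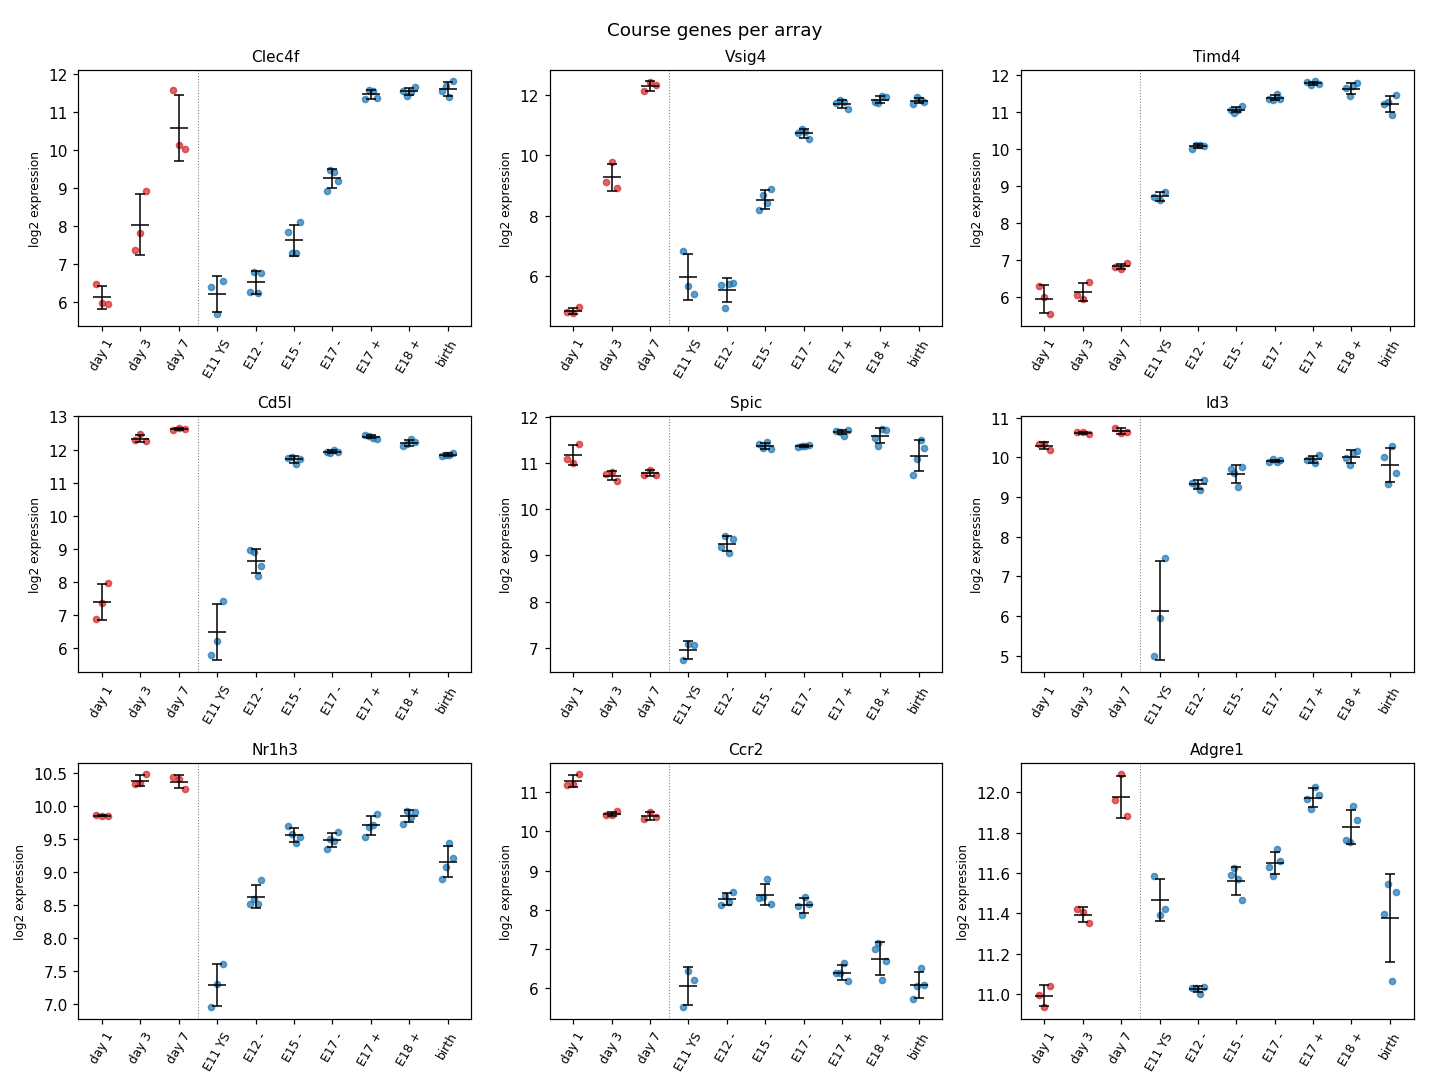
Log2 expression of course genes in each array (points) along the groups, with the group mean and SD in black, repopulation in red and the fetal course in blue. Vsig4 and Cd5l climbed in both courses, Timd4 was at 6.84 ± 0.08 in day-7 cells against 11.21 ± 0.22 at birth, and Ccr2 at 10.39 ± 0.10 against 6.10 ± 0.33.

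The end points of both courses, day-7 Clec4f+ macrophages and Kupffer cells at birth, show how alike the cells are when reached by different routes. Vsig4 and Cd5l differed by less than the minimum change, by 0.48 ± 0.23 and 0.78 ± 0.22, and neither was called. In both genes all day-7 arrays lay above all birth arrays. Timd4 was 20.7-fold lower on day 7, at 6.84 ± 0.08 (n = 3) against 11.21 ± 0.22 (n = 4). Ccr2 was higher on day 7, at 10.39 ± 0.10 against a dim 6.10 ± 0.33, Gbp2b higher by 5.25 ± 0.25, Cd207 by 3.60 ± 0.17 and the fatty acid binding protein gene Fabp7 by 3.25 ± 0.34. Clec4f was lower by a change of -1.02 ± 0.30, a call that rests on single arrays: it was -0.799 and -0.745 without day-7 replicate 2 or 3 and -0.997 and -0.957 without birth replicate 2 or 4, none of them called. It was -1.527 without day-7 replicate 1, and -1.044 and -1.096 without birth replicate 1 or 3, all of them called. The Kupffer cell list split, with 5 of 31 members higher and 6 lower (adjusted p = 0.452 with an estimated correlation; median 0.40, mean -0.02). MHC class II genes were higher on day 7 in 7 of 12, Cd74 by 2.33 ± 0.18 (adjusted p = 0.0179 with an estimated correlation). Cell cycle genes were lower in 29 of 34, Kif11 by -2.59 ± 0.17 (adjusted p = 0.0104 with an estimated correlation). Markers of other cells were lower on day 7. These were 14 of 17 neutrophil and precursor markers (Ngp -7.05 ± 0.18, S100a8 -5.93 ± 0.58, adjusted p = 0.00756 with an estimated correlation), 12 of 16 erythroid markers (Rhag -3.90 ± 0.22, adjusted p = 0.00369) and 7 of 12 B, T and NK cell markers (Vpreb1 -4.52 ± 0.35, adjusted p = 0.0235). Of the hepatocyte markers 9 of 16 were lower and 1 higher, Afp lower by -5.63 ± 0.32 (adjusted p = 0.326 with an estimated correlation). In total 946 genes were called, 236 higher and 710 lower on day 7. The age of the mice differs with the course.

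Over the whole repopulation course, from day-1 monocytes to day-7 Clec4f+ macrophages, Vsig4 rose by 7.45 ± 0.24 from a dim 4.84 ± 0.10, Cd207 by 5.41 ± 0.19, Clec1b by 5.29 ± 0.13, Cd5l by 5.21 ± 0.24 and Clec4f by 4.46 ± 0.32. Of the Kupffer cell list 22 of 31 rose and 1, Id1, fell by 1.08 ± 0.15 (adjusted p = 3.8e-06 with an estimated correlation). Chil3 fell by 6.83 ± 0.37, Serpinb10 by 5.10 ± 0.31 and S100a4 fell by 4.34 ± 0.32, and monocyte genes fell in 8 of 17 (adjusted p = 0.00727 with an estimated correlation). Neutrophil and precursor markers were lower in 8 of 17, Ngp by -3.76 ± 0.19 (adjusted p = 0.136 with an estimated correlation). The complement list rose with 7 of 16 higher and 4 lower, Cd55, a brake on complement, by 3.81 ± 0.23 (adjusted p = 0.00895 with an estimated correlation). Scavenger receptors rose in 6 of 22 (Cd36 by 1.98 ± 0.16, adjusted p = 0.0235 with an estimated correlation), LXR targets in 4 of 17 (Pltp by 1.83 ± 0.11, adjusted p = 0.0412) and pan-macrophage genes in 4 of 18 with 2 lower (adjusted p = 0.0185). The embryonic macrophage list rose too, 8 of 24 against 3 lower, Folr2 by 3.91 ± 0.14 and Ccl24 by 3.21 ± 0.12 (adjusted p = 0.039 with an estimated correlation). Its score went from -1.12 ± 0.04 on day 1 to -0.68 ± 0.13 on day 7 (SD, n = 3 each). That was still below every group of the fetal course, of which E17 Clec4f+ cells were lowest (0.12 ± 0.06). Of its 24 measured members 9 are also in another list, Folr2 in the Kupffer cell list. Endothelial markers rose in 19 of 19, Bmp2 by 3.72 ± 0.30 (adjusted p = 0.0471 with an estimated correlation). In total 744 genes were called, 515 higher and 229 lower, and 378 with the endothelial and hepatocyte scores as covariates.

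Over the fetal course, from E12 Clec4f- macrophages to Kupffer cells at birth, Vsig4 rose by 6.27 ± 0.21 from a dim 5.54 ± 0.40, Clec4f by 5.09 ± 0.28 and Cd5l by 3.21 ± 0.21. Of the Kupffer cell list 23 of 31 rose (adjusted p = 9.65e-06 with an estimated correlation). H2-Aa rose by 5.49 ± 0.26, and 6 of 12 MHC class II genes rose (adjusted p = 0.00211 with an estimated correlation). Complement genes rose in 9 of 16 with 2 lower (C6 by 4.25 ± 0.14, adjusted p = 0.00268 with an estimated correlation), scavenger receptors in 7 of 22 with 2 lower (Cd209f by 4.24 ± 0.34, adjusted p = 0.042), LXR targets in 5 of 17 (Scd1 by 2.94 ± 0.16, adjusted p = 0.0229) and adhesion genes in 8 of 23 with 1 lower (Vcam1 by 3.60 ± 0.14, adjusted p = 0.0434). Fcrls fell by 5.63 ± 0.26, the embryonic globin gene Hbb-bh1 by 5.20 ± 0.39 and F13a1 by 4.04 ± 0.26. Markers of other cells rose with the same groups. These were 15 of 16 hepatocyte markers (Ahsg by 6.10 ± 0.25, adjusted p = 0.0108 with an estimated correlation), 10 of 12 B, T and NK cell markers (Vpreb3 by 4.70 ± 0.19, adjusted p = 0.00247) and 6 of 13 dendritic cell markers with 1 lower (Dpp4 by 3.77 ± 0.25, adjusted p = 0.0297). Endothelial markers were higher in 18 of 19 (Clec4g by 5.78 ± 0.24, adjusted p = 0.0561 with an estimated correlation), and neutrophil markers in 8 of 17, or 9 when adjusted over the list alone (Retnlg by 4.72 ± 0.37, adjusted p = 0.0816). In total 1086 genes were called, 795 higher and 291 lower. The count was 720 when dimmer probes were left out and 100 with the endothelial and hepatocyte scores as covariates.

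**Figure D3:**
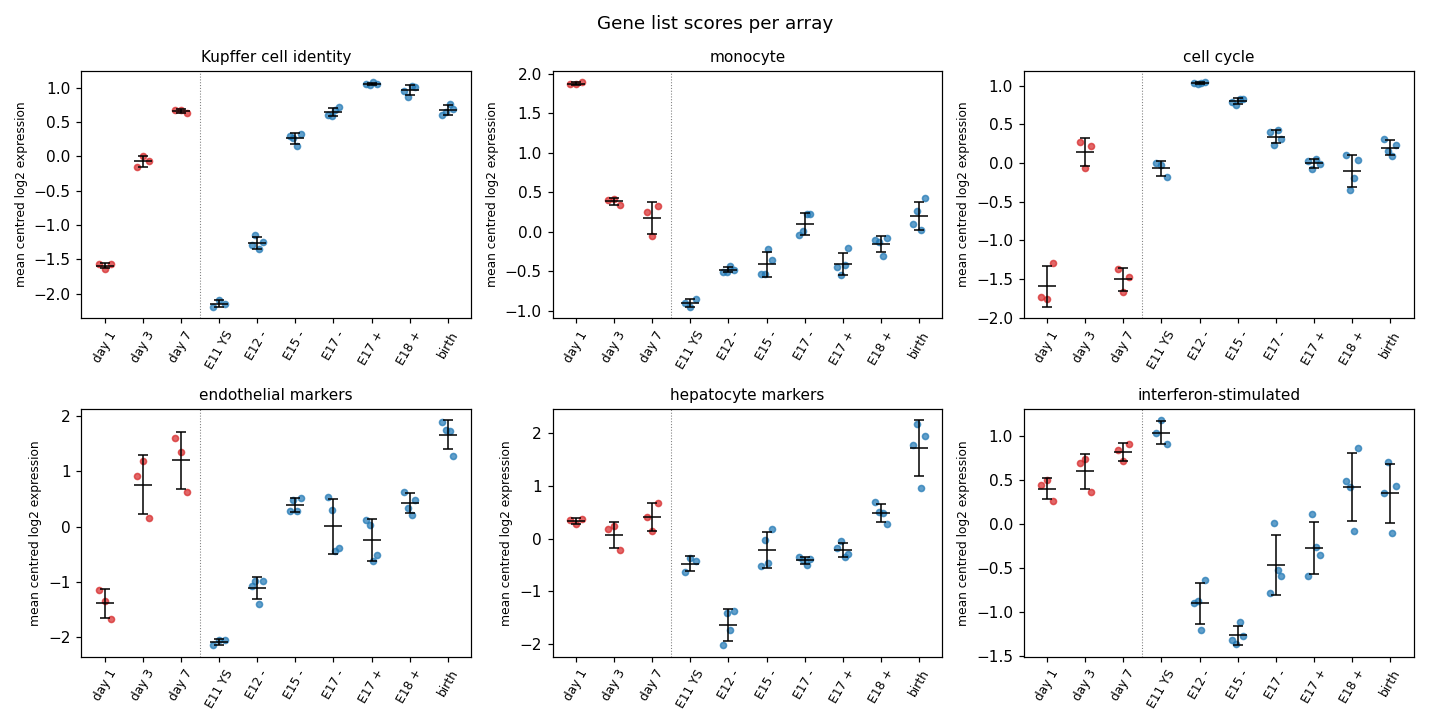
Mean score of selected gene lists in each array (points; each gene centred on its mean over the arrays, log2 units) along the groups, with group mean and SD in black, repopulation in red and the fetal course in blue. The endothelial score went from -1.39 ± 0.27 on day 1 to 1.2 ± 0.51 on day 7 and from -1.11 ± 0.20 at E12 to 1.66 ± 0.26 at birth.

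Both courses gained many genes in common. Of 515 genes that rose in repopulation and 795 that rose in fetal liver, 302 were shared against 36 from the product of the proportions, and 45 were lower in both against 5.9. In opposite directions, 3 genes were higher in repopulation and lower in fetal liver against 13.2 from the product, and 28 were lower in repopulation and higher in fetal liver against 16. Across 11360 genes, which are not independent replicates, the changes of both courses had a Pearson correlation of 0.452 and a Spearman correlation of 0.4. Most endothelial markers were higher over both courses and are among the shared genes. The shared count of 347 was 22 with the endothelial and hepatocyte scores as covariates. The endothelial scores were -1.671 to -1.142 on day 1 and 0.632 to 1.613 on day 7. In the fetal course they were -1.398 to -0.977 at E12 and 1.283 to 1.89 at birth. Since they do not overlap, that fit extrapolates. Its count cannot decide how much of the overlap comes from endothelial or hepatocyte RNA. The same limit holds for the covariate counts of each course and of their difference.

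**Figure D4:**
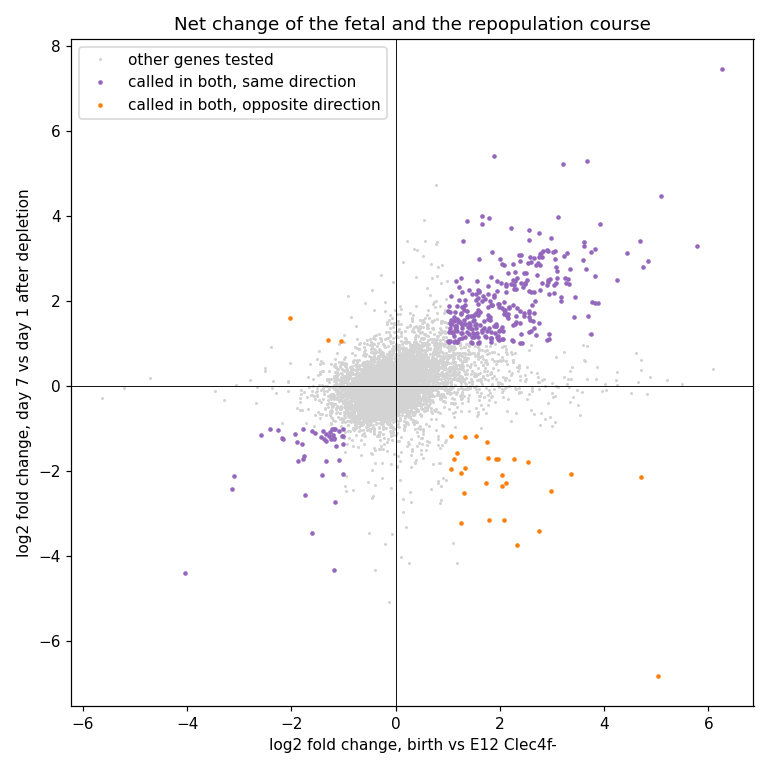
Change over the repopulation course (day 7 minus day 1, log2, vertical axis) against change over the fetal course (birth minus E12, log2, horizontal axis), 1 point per gene. Genes called in the same direction in both, 302 higher and 45 lower, lie in the upper right and lower left.

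The difference between the courses was tested directly as the repopulation change minus the fetal change. Chil3 differed most, by -11.87 ± 0.50, since it fell in repopulation and rose in fetal liver. Retnlg (-6.88 ± 0.56), Lcn2 (-6.17 ± 0.33) and Ngp (-6.09 ± 0.25), genes of neutrophils, followed, whereas Fcrls (5.34 ± 0.40) and Cd207 (3.53 ± 0.25) were on the other side. Among course genes, Cd5l (2.002 ± 0.32, adjusted p = 1.38e-05) and Ccr2 (1.30 ± 0.28, adjusted p = 0.000629) were higher in the repopulation change and Spic was lower (-2.30 ± 0.18, adjusted p = 1.75e-11). Ccr2 went down over both courses, by less in repopulation, and was dim at birth. Vsig4 was called too (1.17 ± 0.32, adjusted p = 0.00632), but both of its starting levels were dim, so that a different change is not shown. Clec4f, Timd4, Nr1h3 and Id3 did not differ past the threshold, with -0.64 ± 0.42, -0.26 ± 0.18, -0.02 ± 0.17 and -0.12 ± 0.39. On day 1 the arrays of Clec4f (5.934 to 6.475) and Timd4 (5.557 to 6.298) lay near or under 6.22, the limit for dim probes. An equal change is therefore not shown for Clec4f and Timd4. The Kupffer cell list had members on both sides, 8 of 31 higher and 6 lower (adjusted p = 0.65 with an estimated correlation). Monocyte genes were lower in 11 of 17 and 1 higher (adjusted p = 0.00151 with an estimated correlation) and MHC class II genes lower in 8 of 12, H2-Aa by -5.45 ± 0.40 (adjusted p = 0.00268). The embryonic macrophage list was higher in 13 of 24 with 2 lower, Folr2 by 3.36 ± 0.18 (adjusted p = 0.00151 with an estimated correlation). Its score went up from -1.12 to -0.68 in repopulation and down from 0.64 at E12 to 0.16 at birth. Markers of other cells were lower in the repopulation change: 15 of 16 hepatocyte markers (Ahsg -5.70 ± 0.38, adjusted p = 0.00719 with an estimated correlation), 11 of 17 neutrophil markers (adjusted p = 0.0104) and 8 of 12 B, T and NK cell markers (Vpreb3 -4.33 ± 0.28, adjusted p = 0.00472). Adjusted over the list alone, 5 interferon-stimulated genes were lower in place of 4 and 3 complement genes higher in place of 2. In total 986 genes were called, 434 higher and 552 lower; with centred arrays, which moved the median of all genes from 0.045 to 0.108, the majority turned, with 513 higher and 505 lower. The count was 655 when dimmer probes were left out and 222 with the endothelial and hepatocyte scores as covariates.

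Over all 12 comparisons and 30 lists, 191 of 360 list tests were called with the preset correlation and 72 with an estimated correlation, all of which were among the 191.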

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

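The tests of hepatocyte gene coherence and of the interferon spread were chosen only after the result was seen, as were the alternatives with marker scores as covariates.

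Endothelial markers were higher at the end of both courses, as the Kupffer cell list was (adjusted p = 0.0471 and 0.0561 with an estimated correlation), but from E18 to birth the scores parted (Kupffer 0.97 ± 0.07 to 0.68 ± 0.07, endothelial 0.42 ± 0.18 to 1.66 ± 0.26; SD, n = 4). From day 1 to day 3 the mean change of the Kupffer cell list was 1.521 ± 0.052 without and 1.534 ± 0.104 with the endothelial and hepatocyte scores as covariates. The covariates act only through variation within groups. The endothelial scores of day 1 (-1.671 to -1.142) and day 3 (0.16 to 1.189) do not overlap. The fit therefore extrapolates and cannot decide whether endothelial or hepatocyte RNA caused that rise. The members that rose went from 17 to 13 with the covariates. Over the fetal course the mean was 1.94 without and 1.969 with them. There 23 rose and 0 fell without the covariates, and 13 rose and 1 fell with them. Within groups the endothelial and Kupffer scores of the 36 arrays had residual correlations of r = -0.036 and rho = -0.077 (permutation p = 0.852, adjusted p = 0.852 over 2 relations), and r = -0.075 without the 2 farthest arrays, and the endothelial genes deviated together (mean residual correlation 0.736) while the Kupffer genes did so little (0.072), which limits this test. A candidate explanation for the endothelial genes is RNA of attached endothelial cells, with Clec4g at 11.50 on day 3 and 11.97 on day 7; the F4/80 and Clec4f gates should remove free endothelial cells, and a macrophage response to the niche stays open and was not tested.

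Hepatocyte markers rose over the fetal course, to 11.96 ± 0.49 for Alb and 11.22 ± 0.51 for Ahsg at birth (SD, n = 4). Within groups the hepatocyte genes had a mean residual correlation of 0.421, against a median of 0.002 and at most 0.098 in 1000 random lists of like expression. Hepatocyte RNA carried into the sorted cells in varying amounts could give this value. Other lists exceeded 0.098 too, among them interferon-stimulated (0.643), cell cycle (0.35) and lysosome genes (0.167). The test therefore cannot separate carried RNA from genes that vary together within the cells, and no conclusion is drawn from it. No hepatocyte marker is in another list. Whether hepatocyte and endothelial RNA come together in the same arrays cannot be told. Their residual scores had r = 0.184 and rho = 0.316 (permutation p = 0.296, adjusted p = 0.593). Without the 2 farthest arrays r was 0.211. Growth of the liver with age may change such RNA, which was not tested.

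Interferon-stimulated genes were high in the E11 yolk sac arrays, although the list was not called against E12 with an estimated correlation. The day-7 scores (0.711 to 0.912) reached the yolk sac range. E12 (-0.90 ± 0.23) and E15 (-1.27 ± 0.11; SD, n = 4 each) were the lowest groups. The gap to E12 therefore also reflects a low level at E12. The scores were 0.91 to 1.179 in the yolk sac arrays and -1.204 to -0.636 in the E12 arrays, 1.94 or 7.44 pooled SDs apart, and the SD in any group was at most 0.39; this argues against random variation from array to array as the whole cause, not against a shared preparation. The median change of the list was -1.728, and -1.916 under quantile normalization and -1.721 with centred arrays, which argues against the scaling of the arrays. Tissue, stage and preparation differ together in these arrays and may each account for it, so no biological explanation was separated from them.

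Among the course genes, 4 passed the interaction test between the courses: the repopulation change minus the fetal change was 1.17 for Vsig4, -2.30 for Spic, 2.0 for Cd5l and 1.30 for Ccr2; both starting levels of Vsig4 (4.84 and 5.54) and the birth level of Ccr2 (6.10) lie under 6.22, the limit for dim probes, so a different change is not shown for Vsig4. In 13 of 234 groups of 4 arrays tested, 1 array lay far from the others, where about 12 arise by chance. The array value of Vsig4 in E12 replicate 2 was 4.94 against 5.712 to 5.761 in the others. The LXR target score was 0.219 in birth replicate 4 (others 0.107 to 0.116) and 0.051 in E15 replicate 3 (0.138 to 0.15). The Notch score of E18 replicate 1 was 0.087 (0.113 to 0.117), and the BMP and TGF-beta score of E12 replicate 4 was 0.052 (-0.027 to -0.014). The MHC class II score of E18 replicate 3 was -0.286 (-0.026 to 0.018), and its B, T and NK cell score was 0.428 (0.928 to 0.956). The scavenger receptor score of E17 Clec4f+ replicate 4 was 0.417 (0.525 to 0.54). The glycolysis score was -0.407 in birth replicate 3 (0.171 to 0.183) and 0.082 in E15 replicate 4 (-0.088 to -0.063). The fatty acid score was 0.357 in birth replicate 3 (0.089 to 0.103), 0.073 in E17 Clec4f+ replicate 2 (0.147 to 0.159) and -0.002 in E18 replicate 2 (0.152 to 0.167).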

How the results depend on the processing

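The covariate fit and the fits without E18 replicate 2 and birth replicate 3 or without the yolk sac arrays were chosen after seeing the data. So were the scalings of the gene lists and the fits of lists of only the E17 fractions. Under the alternatives chosen before the data were examined, 6028 of 6125 values of named genes kept their side of the threshold. Of these values, 63 lost and 34 gained a call and 0 reversed. When single replicates were left out, 5000 of 5149 kept their side, 137 lost and 12 gained a call and 0 reversed. Of 1440 list tests 1209 did, 144 lost and 86 gained a call and 1 reversed: the immediate early and stress list from yolk sac to E12, where fry gave an adjusted p of 0.0354 upward and camera 0.999 downward; fry does not compare with other genes. With an estimated correlation 72 lists were called. A value counted as reversed only where its sign turned and the main or the alternative fit called it. Values that changed sign without a call in either fit count as kept. Many genes were named because the main fit called them, so their stability was partly set in advance.

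Leaving out the minimum change raised every count by construction: 2291 from day 1 to 3, 1951 from day 3 to 7, 6271 from yolk sac to E12, 2738 from E12 to E15, 965 from E15 to E17, 452 between the E17 fractions, 230 from E17 to E18, 2482 from E18 to birth, 4590 between the end points, 3456 and 5426 over the repopulation and fetal courses, 2717 for their difference and 1895 shared. With the stricter filter, which tests fewer genes, 720 were called over the fetal course and 655 for the difference. The E17 to E18 count was 10 with only these groups, 11 with the replicate block and, without E18 replicate 1, 2 or 3, 12, 11 or 43; the cause was not tested. Leaving out single replicates otherwise gave 622 to 694 genes from day 1 to 3, 208 to 341 from day 3 to 7, 1066 to 1275 from yolk sac to E12, 471 to 505 from E12 to E15, 77 to 99 from E15 to E17, 44 to 52 between the E17 fractions, 307 to 386 from E18 to birth, 902 to 1029 between the end points, 734 to 832 and 1064 to 1172 over the courses, 946 to 1042 for the difference and 331 to 365 shared. Without E18 replicate 2 and birth replicate 3 every gene count stayed within 1.5 times. Without the yolk sac arrays every count of other groups did too. Of all groups, the yolk sac arrays correlated least with each other (r = 0.959 to 0.9666), and the first of these fits kept them. Centring the arrays lowered the share of higher genes over the fetal course from 73.2% to 63% (median of all genes -0.084, then -0.182), and for the difference raised it from 44% to 50.4%. The replicate block, where numbers did not pair samples, gave 1112, 490, 77, 333, 954, 745 and 1089 genes for yolk sac to E12, E12 to E15, E15 to E17, E18 to birth, the end points and the courses; the day-3 groups share too few numbers. Among the lists of the E17 fractions with the preset correlation, the block changed the endothelial call and no other; with an estimated correlation limma called 7 lists without and 0 with the block (8 at an unadjusted p under 0.05). The second table equals the first, so it gave no separate values. Signal near the background limits changes from or to dim levels; the filter keeps a gene that is dim in some groups, as in 176 of the 497 changes of named and called genes.

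With the endothelial and hepatocyte scores as covariates limma called 0 genes from E17 to E18 (1184 at an unadjusted p under 0.05), 109 from E18 to birth, 378 and 100 over the repopulation and fetal courses, 222 for the difference and 22 shared. By construction this fit extrapolates where groups differ in the scores by more than their arrays do. This holds over both courses and, between the end points, for the hepatocyte score. Among the steps it holds from day 1 to day 3, from yolk sac to E12 and from E12 to E15. It also holds from E17 to E18 and from E18 to birth. Of 641 values of named genes, 439 kept their side of the threshold, 177 lost and 4 gained a call and 21 reversed. None of the reversed values was called with the covariates. From day 1 to 3 they were Pros1 -0.256, Dpp4 -0.428 and Lyve1 -0.136, and from E12 to E15 Eng -0.229. From E18 to birth Fgb reversed, to -0.20, and over repopulation Eng (-0.081) and Dpp4 (-0.113) did. Over the fetal course they were S100a4 0.837, Eng -0.29, Tgfbr1 0.21, Ifit2 -0.002, C5ar1 0.075, Jam2 -0.736, Rhag -0.125, Sparcl1 -0.835, Gzmb -0.948 and Kit -0.441. For the difference they were Rsad2 0.359, Ifit2 0.509, Fabp7 -0.056 and Rhag 0.246.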

Other observations

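The tests in this part were chosen before their results were seen, but which relabellings gave as many genes as the difference between courses was looked up only afterwards. The BMP and TGF-beta score went from -0.61 ± 0.06 in yolk sac (SD, n = 3) to 0.00 ± 0.04 at E12 (SD, n = 4). Of 23 BMP and TGF-beta genes 7 rose from yolk sac to E12 (adjusted p = 0.115 with an estimated correlation), Id3 and Id1 among them; over repopulation 1 rose and 1 fell and over the fetal course 1 rose and 2 fell, with Eng, which endothelial cells also express, up 2.46 ± 0.27 and 2.30 ± 0.24. In the Notch list (16 measured) Hey1, a Notch target, rose by 1.40 ± 0.22 over repopulation and 1.15 ± 0.19 over the fetal course, and Rbpj, the transcription factor of the pathway, fell by 1.11 ± 0.10 and 1.54 ± 0.09. Hey1 reached 8.96 ± 0.18 in E17 Clec4f+ cells (SD, n = 4), and the Notch list had adjusted p of 0.89 and 0.319 with an estimated correlation over the courses.

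Glycolysis and hypoxia genes were higher at E12 than in yolk sac in 5 of 20 (adjusted p = 0.625 with an estimated correlation) and lower at E15 than at E12 in 3 of 20, Bnip3 by -1.19 ± 0.22 (adjusted p = 0.203 with an estimated correlation). Oxidative phosphorylation genes were higher from yolk sac to E12 in 1 of 27, Ndufs1 (adjusted p = 0.542 with an estimated correlation), and from day 3 to day 7 the list had a median of -0.27 (adjusted p = 0.0716 with an estimated correlation). Ribosome and translation genes were higher from yolk sac to E12 in 2 of 19, Ncl by 1.39 ± 0.13 (adjusted p = 0.195 with an estimated correlation). Fatty acid genes rose in 3 of 20 and fell in 2 over repopulation, Fabp7 up 3.34 ± 0.36 and Pparg down 1.23 ± 0.14 (adjusted p = 0.669 with an estimated correlation). Inflammatory genes were lower from E12 to E15 in 6 of 18 and higher in 1, Ccl12 by -2.35 ± 0.24 (adjusted p = 0.2 with an estimated correlation).

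Whether other splits of the arrays give as many calls was tested with limma fits of the compared groups. In the comparisons with 35 splits only 1 split, the real one, gave as many genes. A share of 1 of 35 is the smallest this test can give, and it was not adjusted over the comparisons. It shows that other groupings of these arrays gave fewer calls but does not exclude chance. The real count and the highest other were 1150 and 0 from yolk sac to E12, 489 and 0 from E12 to E15, 81 and 4 from E15 to E17, 10 and 4 from E17 to E18, 331 and 0 from E18 to birth, 935 and 148 between the end points and 1089 and 0 over the fetal course. Between the E17 fractions, whose numbers pair, 8 splits part every pair, too few for a share under 0.05: the real count was 46 and the highest other 0, and the other 27, which do not part every pair, gave at most 4. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05: from day 1 to day 3 the real count was 631 and the highest other 1, from day 3 to day 7 they were 221 and 0, and over repopulation 737 and 0. For the shared genes 1 of 100 relabellings, the real grouping, gave 347 and the highest other was 1. Other splits of either course alone called at most 0 genes, so an overlap near 0 was set in advance. These relabellings therefore do not show whether the overlap exceeds what the genes called in each course would give. For the lists 1 of 100 gave 191 and the highest other was 149, so the other drawn groupings of all arrays gave fewer called lists. For the difference between courses 4 of 100 gave as many as the real 987, and the highest other was 1337. The 3 others as large each exchanged all 8 fetal arrays between E12 and birth, which turns the sign of the fetal change, so these relabellings say nothing about chance for this count.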
